A study of Mus musculus with 12 samples.

How the data were processed

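RNA sequencing was used to measure gene expression in primary mouse bone marrow-derived macrophages, cultured from tibial marrow of mice aged 6 to 8 weeks per the labels. There were 12 libraries in 4 groups of 3: wild type (WT) and Kif13b-deficient (KO) macrophages, each without or with apoptotic Jurkat cells, a human T cell leukaemia line. The co-culture lasted 90 min at a ratio of 1 macrophage to 5 apoptotic cells. The labels name the altered genotype both as homozygous null and as a knock down, and KO stands for the libraries so labelled. Per the labels, serum was 10, 10 and 11% for the WT and 12, 13 and 14% for the KO libraries without apoptotic cells, and no percentage is used here for the others. From WT 2 on these values rise by 1 per library, as when a spreadsheet column is filled down, so they are in doubt. Nothing in the labels says whether the 3 libraries of a group came from separate animals or separate cultures, so p-values measure only the spread between these libraries.

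The deposited tables hold raw read counts per gene symbol, with 1 column per library and no normalisation. Per the submitters' processing notes the tools were fastp, HISAT2 2.0.5 and DESeq2 1.20.0, with the mouse genome mm10. The counting tool, its annotation and its strand setting are not given in the sources used here. One table holds the 6 libraries without apoptotic cells (54957 symbols) and the other the 6 libraries with them (55367 symbols), so the condition and the table are the same split of the libraries. The tables share 54582 symbols, and 375 and 785 symbols stand in one table alone, with 0.247% and 1.49% of that table's counts. No column of either table was left unused. Some genes of the fixed lists, among them Vegfa, Junb, Myc and Tpi1, were not analysed here without apoptotic cells, because their symbols were not matched in that table.

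Total counts ran from 18256622 to 18770757 per library without and from 17000976 to 17285594 with apoptotic cells. Symbols were matched by exact name to the GENCODE vM21 annotation of GRCm38 for exonic length, GC content, biotype and position, with 53202 and 53186 symbols matched to 1 gene. These properties did not enter the tests unless a correction is named.

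Each comparison was fitted in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust, two-sided), after filterByExpr by group and TMM scaling. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. KO was compared with WT inside each table. The effect of apoptotic cells in each genotype, and the interaction of genotype and apoptotic cells, were taken from 1 joint fit of the 12 libraries on the shared symbols. Values are counts per 1e6 counts of the scaled library (CPM) as mean ± SD over the 3 libraries of a group, scaled within the fit they come from, so CPM of the same library differ slightly between fits. Fold changes are log2, with the standard error (SE) derived from the test statistic.

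A set of 32 gene lists with 607 members, of which 599 were matched without apoptotic cells, covered efferocytosis, inflammation, metabolism, stress, the cell cycle and markers of other cell types. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Members of each list were counted after adjustment over all genes tested and adjusted over the list alone. The named genes are Kif13b, Mertk, the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM and groups that did not overlap (5 each way for the interaction, where overlap was not asked), and up to 4 members of each list with the smallest p. Predicted genes, pseudogenes, ribosomal and mitochondrial genes and receptor segments were kept out of the largest changes. A gene that this rule names is not reported here.

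A fold change against a group in which no library had a count was computed as a lower bound, from 3 counts in each of its libraries. A ratio against 1 to 3 counts in a group carries a 95% exact binomial (Clopper-Pearson) interval. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The similarity of the KO effect in the 2 conditions was the correlation across genes of the log2 fold changes of the 2 separate fits, and genes are not independent replicates. Called genes within 10 Mb of Kif13b were compared with the rest by a two-sided Fisher's exact test.

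The alternatives set beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter, a block for the replicate number, at least a 2-fold change, a joint fit or a fit of the 6 compared libraries, leaving out each library in turn, the other list tests, a filter at 10 CPM for the similarity and a window of 20 Mb. After the data were seen, a length correction, a length and GC correction (a natural spline with 4 degrees of freedom per library, used as an offset), a fit without KO libraries 1 and 2, and a restriction to genes with at least 1 CPM without apoptotic cells were added. Groups were also split in other ways, in all 10 splits of 6 libraries or 60 drawn ones for the interaction.

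The code was tested on simulated counts with 200 changed genes per comparison, drawn from the fitted means and dispersions. In the test without apoptotic cells, 62% of 1.5-fold and 99% of 2-fold changes were recovered, with 8 false among 169 calls. With length and GC trends of the libraries added to this simulation, 420 of 605 calls were false (69.4%), and 15 of 209 (7.18%) after the length and GC correction. The added trends had the form that the correction removes. With apoptotic cells and no added trends, 88% of 1.5-fold and 99% of 2-fold changes were recovered, with 20 false among 207 calls. For the interaction these shares were 43% and 84%, with 5 false among 132 calls. No list was called in these 5 simulated comparisons. Genes were drawn independently there, so this cannot show how the list tests behave where genes of a list vary together. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.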

Results

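RNA sequencing of primary mouse bone marrow-derived macrophages compared wild type (WT) cells with cells labelled as lacking KIF13B (KO), a kinesin motor protein that carries cargo along microtubules. Each genotype was measured without and with apoptotic Jurkat cells (AC), a human T cell leukaemia line that served as the material to be engulfed. Each of the 4 groups had 3 libraries. The series asks whether macrophage KIF13B bears on efferocytosis, the clearance of apoptotic cells, through the receptor MERTK. Total counts were 18351051 to 18770757 in the KO, 18256622 to 18461359 in the WT, 17160248 to 17285594 in the KO + AC and 17000976 to 17256902 in the WT + AC libraries. Libraries with apoptotic cells had counts for 31787 to 32801 symbols, against 18335 to 18540 without. Spread between libraries differed as well, since the common biological coefficient of variation was 0.117 without and 0.0294 with apoptotic cells. Pairs of libraries within a group were compared with sampling noise by a chi-square of their counts. Per degree of freedom it was 1.47 to 2.09 with apoptotic cells, little above sampling noise, and 5.35 to 38.7 without. Whether the libraries of a group were separate cultures is not known, so the small p-values with apoptotic cells may not extend to other cultures.

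The first comparison asks how the targeted gene and the receptor of interest were expressed. Kif13b (GRCm38 chromosome 14, 64647265 to 64809617, plus strand) had 281, 345 and 424 counts in the KO libraries and 599, 546 and 535 in the WT libraries. This was 19.5 ± 2.88 CPM against 29.4 ± 1.22 (SD, n = 3 each), a log2 fold change of -0.59 (edgeR adjusted p = 0.0087). With apoptotic cells it had 1697, 1697 and 1721 counts in the libraries labelled KO and 1600, 1561 and 1634 in WT, or 101 ± 0.33 against 92.3 ± 2.81 CPM. Here Kif13b was higher in the libraries labelled KO (log2 0.13, adjusted p = 0.0261), against the genotype on the label, and the interaction was 0.74 on the log2 scale (adjusted p = 0.000815). Counts over the whole gene do not tell a null allele from an intact one where the altered transcript is still made. Mertk (chromosome 2, 128698956 to 128802894, plus strand), the efferocytosis receptor, had 63.0 ± 11.2 CPM in KO and 61.9 ± 8.51 in WT (log2 0.02, SE 0.14, adjusted p = 0.922). With apoptotic cells it had 50.4 ± 1.38 and 49.96 ± 2.52 CPM (log2 0.01, SE 0.05, adjusted p = 0.926), and no interaction was called (log2 0.01, SE 0.16). These are RNA levels, and the amount of MERTK protein or its place in the cell was not measured here. Mfge8 (chromosome 7, 79133768 to 79149060, minus strand), a secreted protein that bridges phosphatidylserine on dying cells to integrins, was higher in KO without apoptotic cells. It had 4135 ± 248 CPM against 1797 ± 164 (log2 1.202, adjusted p = 1.23e-05). With apoptotic cells it was lower in the libraries labelled KO, at 709 ± 22.0 against 1080 ± 43.6 CPM (log2 -0.61, adjusted p = 4.8e-19). The Kif13b call ended without KO library 1 (log2 -0.48, adjusted p = 0.0624, range over the alternatives 0.000227 to 0.293). With apoptotic cells it ended without KO + AC library 1 (0.0765) or 2 (0.0612), without WT + AC library 2 (0.147) and with DESeq2 or the joint fit, over a range of 0.00172 to 0.671.

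**Figure D1:**
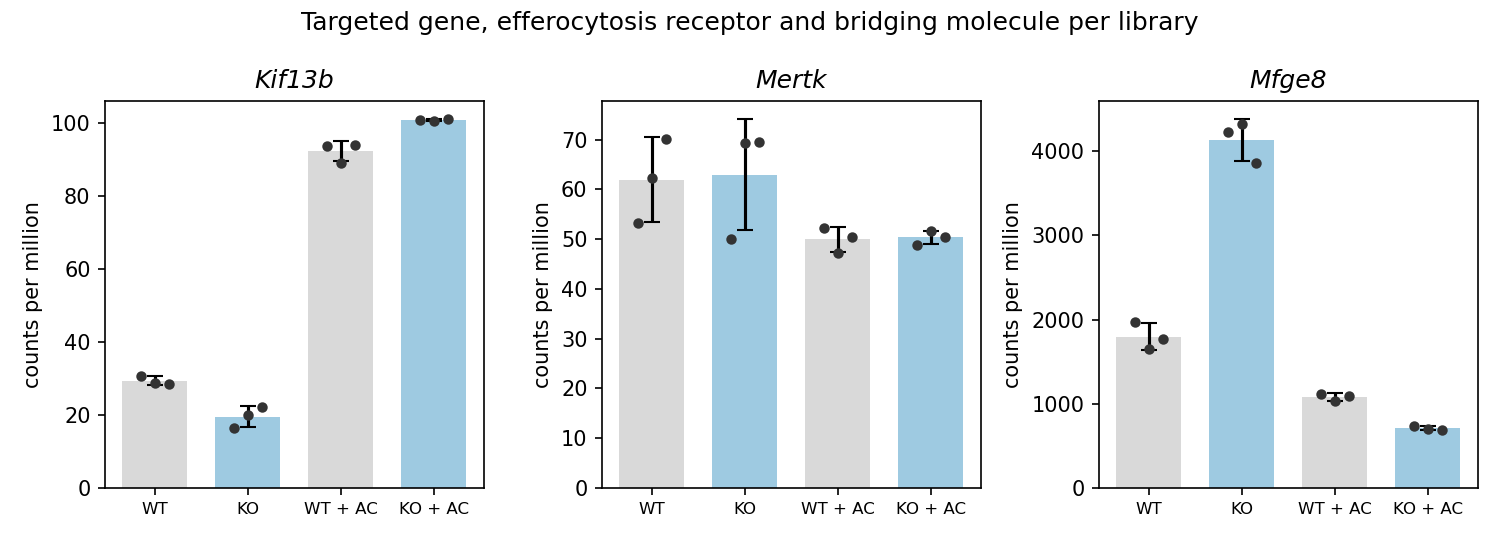
CPM of Kif13b, Mertk and Mfge8 in the 4 groups, where AC marks co-culture with apoptotic Jurkat cells, points are libraries, bars are means of 3 libraries and error bars are SD. Kif13b had 19.5 CPM in KO and 29.4 in WT but 101 in KO + AC and 92.3 in WT + AC, and Mfge8 went from 4135 in KO and 1797 in WT to 709 and 1080.

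Without apoptotic cells, fibroblast and stromal markers and matrix genes were higher as lists in the libraries labelled KO, and alternative activation genes and NF-kB targets were lower, by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.422 to 0.521). The labels give serum of 10, 10 and 11% for the WT and 12, 13 and 14% for the KO libraries, so on the labels serum and genotype coincide here, but from WT 2 on the values rise by 1 per library and are in doubt. Acta2, smooth muscle actin, had 178 ± 32.7 CPM in KO and 55.8 ± 4.71 in WT (log2 1.68, SE 0.14, n = 3 each). The largest changes, here and below, are taken among called genes with a mean of at least 2 CPM. Except for the interaction, their groups also did not overlap. Called genes outside this rule, such as Adgre4 (-1.98), are not ranked here. The largest rise was in Sfrp5, a secreted Wnt antagonist (14.995 ± 1.02 against 4.06 ± 0.457 CPM, log2 1.88, SE 0.16), followed by Igfbp2 (1.79), Acta2, Myl9 (1.52), Clca3a1 (1.44), Nnat (1.41), Mest (1.33), Fbln5 (1.32), Htr2b (1.27) and Tmem178 (1.24). The largest fall was in Fpr1, a receptor for formylated peptides (2.25 ± 0.449 against 8.72 ± 0.955 CPM, log2 -1.95, SE 0.19). It was followed by Asap2 (-1.84), the condensin II subunit Ncapg2 (-1.84, 11.3 ± 2.39 against 40.6 ± 5.73 CPM), Ms4a4a (-1.66), the coagulation factor F13a1 (-1.52), Hpgd (-1.38), Serpinb2 (-1.30), Ednrb (-1.26), Calcrl (-1.22) and Clec2g (-1.21). In all, 2045 of 12640 genes were called, 1004 higher and 1041 lower in KO, with a median absolute log2 fold change of 0.553 and 160 genes changed at least 2-fold (106 higher, 54 lower). KO library 3 was closer to WT 1 (chi-square of the counts per degree of freedom 9.08) than to KO 1 (24.8) or KO 2 (38.7), so it resembled that WT library more than its own group. The groups did not overlap for 33.6% of genes, where chance gives 10%.

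Of the 29 lists tested without apoptotic cells, 8 were called by camera. Fibroblast and stromal markers had 7 of 12 members higher and 0 lower (8 higher adjusted over the list alone, camera adjusted p = 5.08e-08, adjusted p = 0.422 with an estimated correlation). They included Acta2, the collagen Col3a1 (log2 1.00, 89.4 ± 17.3 against 44.6 ± 6.53 CPM) and the chemokine Cxcl12 (0.66). Extracellular matrix genes had 7 of 24 higher and 3 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.521 with an estimated correlation), among them Col3a1 and Col4a1 (0.61). Osteoclast markers had 2 of 7 higher (also 2 adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.422 with an estimated correlation), the acid phosphatase Acp5 (1.02) and the protease Ctsk (0.89, 559 ± 82.4 against 302 ± 12.7 CPM). Cell cycle genes had 10 of 32 higher and 0 lower (12 adjusted over the list alone, camera adjusted p = 0.00297, adjusted p = 0.422 with an estimated correlation). Cdc20 was at 0.76. Without KO library 3, 3 of these 8 lists kept their calls, and the calls ended for the cell cycle (adjusted p = 0.0772), matrix (0.206), osteoclasts (0.0772), alternative activation (0.0772) and NF-kB targets (0.0777), as did leaving out WT 1 for alternative activation (0.078) and WT 2 for osteoclasts and NF-kB targets (0.0571). Nuclear genes of oxidative phosphorylation had 9 of 26 higher (11 adjusted over the list alone, camera adjusted p = 0.000606, adjusted p = 0.739 with an estimated correlation). Without KO libraries 1 and 2 their median went from 0.26 to 0.0062 (adjusted p = 0.791, range over the alternatives 2.64e-06 to 0.791). The shortest genes had a median of 0.29, so the 0.26 of this list does not by itself separate it from the trend with length. Its call was kept with the length and GC correction. Mitochondrially encoded genes went the other way from the nuclear ones, with 7 of 13 lower (11 adjusted over the list alone, median log2 -1.13, camera adjusted p = 6.11e-08, adjusted p = 0.521 with an estimated correlation). The mitochondrial share of counts was 1.11%, 0.578% and 1.23% in the KO libraries and 1.42%, 2.05% and 2.52% in the WT libraries. NF-kB targets and cytokines had 3 of 17 lower (8 adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.422 with an estimated correlation). Alternative activation genes had 5 of 15 lower (6 adjusted over the list alone, camera adjusted p = 0.0194, adjusted p = 0.422 with an estimated correlation), including Arg1, which turns arginine into ornithine (log2 -0.95, 59.0 ± 8.96 against 114 ± 8.23 CPM).

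Among genes of apoptotic cell clearance, no common direction was found without apoptotic cells. Receptors and bridging molecules had 1 of 29 higher, Mfge8, and 4 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.956), including the scavenger receptor Marco (log2 -1.15, 4.63 ± 0.899 against 10.3 ± 1.87 CPM). Engulfment and LC3-associated phagocytosis genes had 1 of 29 higher, Map1lc3a (0.73), and 3 lower (also 1 and 3 adjusted over the list alone, camera adjusted p = 0.057). Map1lc3a was at 0.30 after a length and GC correction (adjusted p = 0.0709) and at 0.36 without KO libraries 1 and 2 (adjusted p = 0.333, range over the alternatives 3.99e-05 to 0.333). Other transport kinesins had 2 of 22 higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.577). Monocyte markers had 1 of 7 higher, Plac8, and 3 lower, with F13a1 at 7.59 ± 0.403 against 21.9 ± 1.86 CPM (1 and 4 adjusted over the list alone, camera adjusted p = 0.057). The log2 fold changes fell with exonic length (r = -0.389 across genes, with a median of 0.29 in the shortest and -0.23 in the longest 8th of the genes). KO libraries 1 and 2 carried this trend (r = -0.533 and -0.302 per library), while KO 3 was at 0.317 and the WT libraries at 0.204 to 0.368. A correction for length and GC, chosen after seeing the data, left 740 called genes, of which 489 were among the 2045 and 488 had the same direction. Single libraries decided the count: it was 312 without KO library 1, 698 without KO 2, 4166 without KO 3, 1001 without WT 2, 370 without WT 3 and 95 without KO 1 and 2 together, when Nnat, Mest, Ms4a4a, Hpgd and Calcrl lost their calls and 15 of the 20 largest changes kept them.

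With apoptotic cells, genes of antigen presentation on MHC class II were higher and genes of the matrix and the cell cycle were lower in the libraries labelled KO. With an estimated correlation the class II list alone was called (adjusted p = 0.0229), and matrix genes (adjusted p = 0.0716) and the cell cycle (adjusted p = 0.177) were not. The class II list also holds Cd80, Cd83, Cd86 and Cd274, which are not class II genes. H2-Ab1, a class II chain, had 282 ± 9.98 CPM against 164 ± 2.83 (log2 0.78, SE 0.04, n = 3 each). The largest rise was in Mid1 (log2 1.40, SE 0.13, 8.85 ± 0.134 against 3.35 ± 0.409 CPM), followed by the formyl peptide receptor Fpr2 (1.05), haptoglobin Hp (1.01), Ly6i (0.93), the cytokine Tnfsf15 (0.91), Fpr1 (0.89), Calhm6 (0.87), Ms4a4a (0.81), H2-Ab1 and Adgre4 (0.77). The largest fall was in Col24a1 (log2 -1.22, SE 0.20, 1.63 ± 0.353 against 3.83 ± 0.513 CPM). It was followed by Tmem267 (-1.09), the cadherin Cdh3 (-1.03), the metalloreductase Steap4 (-0.94), the coagulation factor F5 (-0.93), Htr2b (-0.90), Rian (-0.87), Cxadr (-0.87) and Cdh1 (-0.86). In the joint fit Calhm6 (adjusted p = 0.262) and Cdh1 (adjusted p = 0.063) lost their calls. In all, 1866 of 16467 genes were called, 1083 higher and 783 lower, with a median absolute log2 fold change of 0.226 and 28 genes changed at least 2-fold (7 higher, 21 lower). With the length correction 1784 were higher and 632 lower, so the balance of directions depended on it. The groups did not overlap for 26.4% of genes, where chance gives 10%.

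Of 32 lists, 14 were called with apoptotic cells, and the class II list alone was called also with an estimated correlation. It had 9 of 11 members higher and 0 lower (10 adjusted over the list alone, median log2 0.37, camera adjusted p = 4.24e-46, adjusted p = 0.0229 with an estimated correlation). Cd74 was at 0.73, H2-Eb1 at 0.74 and H2-Aa at 0.70. Extracellular matrix genes had 15 of 24 lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 4.81e-22, adjusted p = 0.0716 with an estimated correlation), such as Col1a2 (-0.62, 111 ± 3.72 against 170 ± 8.47 CPM), Sparc (-0.63) and Col6a1 (-0.69). Fibroblast and stromal markers had 7 of 11 lower (also 7 adjusted over the list alone, camera adjusted p = 7.53e-19, adjusted p = 0.0716 with an estimated correlation), among them Pdgfra (-0.69). Cell cycle genes had 20 of 32 lower and 1 higher (26 and 1 adjusted over the list alone, camera adjusted p = 1.41e-11, adjusted p = 0.177 with an estimated correlation). Top2a was at -0.26 and Mcm5 at -0.28, while the proliferation marker Mki67 was higher (0.32), and these 3 lost their calls in the joint fit (adjusted p = 0.477, 0.264 and 0.196). Osteoclast markers had 6 of 8 lower and 1 higher (also 6 and 1 adjusted over the list alone, camera adjusted p = 6.7e-05, adjusted p = 0.177 with an estimated correlation). Ctsk was at -0.47. Monocyte markers had 2 of 10 higher, Hp and F13a1 (also 2 adjusted over the list alone, camera adjusted p = 0.00292, adjusted p = 0.177 with an estimated correlation).

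Receptors and bridging molecules of efferocytosis had 11 of 31 members higher and 3 lower in the libraries labelled KO + AC (14 and 4 adjusted over the list alone, camera adjusted p = 1e-04, adjusted p = 0.376 with an estimated correlation). Thbs1, a bridging thrombospondin, was at log2 0.40 (516 ± 17.6 against 391 ± 15.3 CPM), Marco at 0.59 and C1qa at 0.30, and Mfge8 was lower. Engulfment and LC3-associated phagocytosis genes had 5 of 29 higher (6 adjusted over the list alone, camera adjusted p = 0.00953, adjusted p = 0.424 with an estimated correlation). The NADPH oxidase chain Cybb was at 0.25. Lysosome genes had 13 of 27 higher and 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 0.000169, adjusted p = 0.555 with an estimated correlation), with the cathepsins Ctss at 0.20 and Ctsl at -0.29. LXR targets had 5 of 14 higher and 3 lower (also 5 and 3 adjusted over the list alone, camera adjusted p = 0.00953, adjusted p = 0.177 with an estimated correlation), including Apoe (0.29) and Mylip (0.43). NF-kB targets had 8 of 25 higher and 2 lower, the chemokines Ccl2 (-0.56) and Ccl7 (-0.54) (13 and 2 adjusted over the list alone, camera adjusted p = 0.00298, adjusted p = 0.555 with an estimated correlation). Interferon-stimulated genes had 8 of 27 higher and 1 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.00481, adjusted p = 0.424 with an estimated correlation). Ccl5 was at 0.44. Immediate early genes had 7 of 27 higher and 2 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.00953, adjusted p = 0.351 with an estimated correlation). Klf2 was at 0.40. Genes of lipid-associated macrophages had 3 of 17 higher and 5 lower (6 each way adjusted over the list alone, camera adjusted p = 0.0296, adjusted p = 0.555 with an estimated correlation), with osteopontin Spp1 at -0.53 and Mmp12 at -0.34. That call was kept in 2 of 12 alternatives. It ended with DESeq2 size factors (adjusted p = 0.107), with the length correction (0.367) or the length and GC correction (0.327), under which the median turned to 0.02, and without KO + AC library 2 (0.0561) or 3 (0.142) or WT + AC 1 (0.108) or 3 (0.178), over a range of 0.000682 to 0.555. The call of NF-kB targets ended without WT + AC 2 (0.051). DESeq2 called 1137 genes, 853 of them higher, the joint fit called 157, and 1192 were called without KO + AC library 1. The joint fit ended 69 of 106 calls of named genes, here those of C1qa, Cybb, Apoe, Ccl5, Ctsl, Ctss and Mmp12.

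Flanking sequence of a targeted allele can carry other changes, so called genes were counted around Kif13b. Without apoptotic cells, 23 of 145 tested genes within 10 Mb were called, or 15.9% against 16.2% of the other genes (odds ratio 0.976, 95% interval 0.595 to 1.54, Fisher's exact p = 1). With apoptotic cells, 28 of 196 were called, or 14.3% against 11.4% (odds ratio 1.30, 0.835 to 1.95, Fisher's exact p = 0.213).

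The effect of apoptotic cells in WT macrophages was led by inflammatory cytokines. Il1b, the precursor of interleukin 1 beta, had 1082 ± 63.1 CPM with and 0.468 ± 0.072 without apoptotic cells (log2 11.15, SE 0.15, n = 3 each), Tnf 1884 ± 98.4 against 14.4 ± 0.273 (log2 7.03) and the neutrophil chemoattractant Cxcl2 1464 ± 48.2 against 2.74 ± 0.784 (log2 9.06). All 25 tested NF-kB targets and cytokines were higher (also 25 adjusted over the list alone, median log2 5.13, or 4.09 with the 1 member at no count set to its bound, camera adjusted p = 3.95e-16, adjusted p = 0.0543 with an estimated correlation). Immediate early genes had 19 of 25 higher and 6 lower (also 19 and 6 adjusted over the list alone, camera adjusted p = 0.00868, adjusted p = 0.164 with an estimated correlation), such as Maff (3.41) and Nr4a1 (4.38). Nr4a3 was 630-fold higher than 1 count in the WT libraries together (95% interval 113 to 24900). Nuclear genes of oxidative phosphorylation had 26 of 26 lower (also 26 adjusted over the list alone, median log2 -1.59, camera adjusted p = 3.21e-09, adjusted p = 0.324 with an estimated correlation). Cox6c was at -2.09 and Cox7a2 at -1.95. The shortest 1440 genes with at least 1 CPM without apoptotic cells had a median of -1.26. The list's median alone therefore does not separate its fall from the trend with length. Its call was kept in 11 of 12 alternatives, the length corrections among them. Mitochondrially encoded genes had 9 of 13 lower (also 9 adjusted over the list alone, camera adjusted p = 0.0283, or 0.0699 without WT library 3, adjusted p = 0.749 with an estimated correlation, range over the alternatives 0.00109 to 0.749). Lysosome genes had 23 of 27 lower and 1 higher (also 23 and 1 adjusted over the list alone, camera adjusted p = 3.71e-06, adjusted p = 0.164 with an estimated correlation). The protease Lgmn was at -1.55. Genes of lipid-associated macrophages had 15 of 17 lower and 1 higher (also 15 and 1 adjusted over the list alone, camera adjusted p = 1.58e-05, adjusted p = 0.324 with an estimated correlation). Apoe was at -2.24 and Fabp5 at -1.98. Interferon-stimulated genes had 17 of 27 lower and 7 higher (also 17 and 7 adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.424 with an estimated correlation), a call that ended with a length correction (adjusted p = 0.0714, range over the alternatives 3.43e-05 to 0.424).

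Efferocytosis receptors and bridging molecules went both ways in WT, with 12 of 31 higher and 15 lower (also 12 and 15 adjusted over the list alone, camera adjusted p = 0.42). The scavenger receptor Olr1 was at log2 7.99 (422 ± 11.3 against 1.65 ± 0.552 CPM) and Thbs1 at 2.01, while the complement chain C1qc was at -2.60 and Cd300a at -1.78. Mertk fell by 0.73 on the log2 scale (43.4 ± 2.08 against 72.0 ± 9.68 CPM, adjusted p = 8.25e-07), and Kif13b was higher (log2 1.23, 80.1 ± 2.17 against 34.2 ± 1.51 CPM), or 0.16 after a length correction. T cell markers, which the Jurkat cells carry, had 12 of 15 higher and 2 lower (also 12 and 2 adjusted over the list alone, median log2 5.28, or 5.11 with 2 members at their bounds, camera adjusted p = 0.00302, adjusted p = 0.118 with an estimated correlation). The kinase Lck had 26.1 ± 2.18 CPM against 0.751 ± 0.183 and Zap70 21.3 ± 2.77 against 0.102 ± 0.128. Genes whose coding sequence is nearly identical in human and mouse had 22 of 31 lower and 2 higher (also 22 and 2 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.615 with an estimated correlation). The ubiquitin gene Ubb was at -1.95. Among genes without a count in WT, for which a rise has only a lower bound and no rank, Gstp3 was at least 188-fold higher, Rn7s2 at least 115-fold, Oprm1 79.2-fold, Rn7s1 77.4-fold, the T cell receptor adaptor Skap1 74.4-fold, the interleukin 12 subunit Il12a 72.8-fold, Stmn3 64.2-fold, Dsp 46.6-fold and Slc4a10 45.9-fold. These bounds cover counting error only. A difference between the 2 tables could give such rises as well and cannot be told apart from the apoptotic cells. The largest falls were in Angptl7 (log2 -5.82, 1.09 ± 0.188 against 61.8 ± 7.35 CPM), Rgs2 (-5.46), Fbxo32 (-5.31), Upk3b (-4.98), Gadd45g (-4.68), Plxna4os1 (-4.66), Nkain4 (-4.65), Rab19 (-4.41), Sh2d1b1 (-4.40) and Ptn (-4.40).

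In WT, 14286 of 16810 genes were called, 8125 higher and 6161 lower, and 9221 changed at least 2-fold. Among genes with at least 1 CPM without apoptotic cells the balance turned, with 3682 higher and 5942 lower. The groups did not overlap for 86.6% of genes, where chance gives 10%. All of these libraries with apoptotic cells stand in 1 table and all without in the other, so a difference between the tables cannot be told apart from the apoptotic cells. The log2 fold changes rose with exonic length (r = 0.323 across genes with at least 1 CPM without apoptotic cells), and 660 to 731 olfactory receptor symbols had counts with apoptotic cells against 20 to 27 without. The median of all genes was 0.25, or 0.36 with DESeq2 size factors and -0.17 with a length correction, which left 14181 called genes with 44.6% of them higher.

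In the libraries labelled KO, inflammatory cytokines also led the effect of apoptotic cells. Interferon-stimulated genes (camera adjusted p = 0.122) and mitochondrially encoded genes (0.414), called in WT, were not called here, and fibroblast and stromal markers, called here, were not called in WT (0.0742). The interaction was called for mitochondrially encoded genes (adjusted p = 0.494 with an estimated correlation) and for fibroblast and stromal markers (adjusted p = 0.073 with an estimated correlation), so neither was called with an estimated correlation. It was not called for interferon-stimulated genes (camera adjusted p = 0.301, adjusted p = 0.646 with an estimated correlation). Il1b had 1275 ± 63.7 CPM with and 0.218 ± 0.0442 without apoptotic cells (log2 12.47, SE 0.17), and Cxcl2 1594 ± 77.9 against 1.08 ± 0.33 (log2 10.51). All 25 NF-kB targets and cytokines were higher (also 25 adjusted over the list alone, median log2 4.81, camera adjusted p = 2.32e-13, adjusted p = 0.0928 with an estimated correlation), and immediate early genes had 20 of 25 higher and 5 lower (also 20 and 5 adjusted over the list alone, camera adjusted p = 0.00586, adjusted p = 0.235 with an estimated correlation). All 26 nuclear genes of oxidative phosphorylation were lower (also 26 adjusted over the list alone, median log2 -1.73, camera adjusted p = 9.67e-10, adjusted p = 0.416 with an estimated correlation). The shortest 1440 genes had a median of -1.49, so here too the list's median alone does not separate its fall from the trend with length. Its call was kept with the length corrections. Lysosome genes had 22 of 27 lower and 2 higher (also 22 and 2 adjusted over the list alone, camera adjusted p = 7.27e-06, adjusted p = 0.235 with an estimated correlation). Genes of lipid-associated macrophages had 16 of 17 lower and 1 higher (also 16 and 1 adjusted over the list alone, camera adjusted p = 1.14e-05, adjusted p = 0.369 with an estimated correlation). Fibroblast and stromal markers had 9 of 12 lower and 1 higher (also 9 and 1 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.419 with an estimated correlation). Acta2 was at -3.69 and Cxcl12 at -4.17. T cell markers had 12 of 15 higher and 2 lower (also 12 and 2 adjusted over the list alone, median log2 5.64, or 4.45 with 2 members at their bounds, camera adjusted p = 0.0119, adjusted p = 0.235 with an estimated correlation). Genes nearly identical in human and mouse had 20 of 31 lower and 5 higher (also 20 and 5 adjusted over the list alone, camera adjusted p = 0.00603, adjusted p = 0.638 with an estimated correlation).

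Mfge8 fell from 4800 ± 267 to 625 ± 19.5 CPM in the libraries labelled KO (log2 -2.94), and Mertk fell by 0.72 on the log2 scale (44.4 ± 1.15 against 73.1 ± 13.1 CPM, adjusted p = 1.04e-06). Olr1 was at log2 9.08 and the integrin chain Itgav at 2.75, within a receptor list that had 13 of 31 higher and 16 lower (also 13 and 16 adjusted over the list alone, camera adjusted p = 0.473). Among genes without a count in KO, Plet1 was at least 153-fold higher with apoptotic cells, the T cell transcription factor Lef1 at least 135-fold, Il12a 101-fold, Rn7s1 75.5-fold, Stmn3 58.8-fold, Oprm1 57.4-fold, Myb 56.4-fold and Tpi-rs5 37.2-fold. Here too the bounds cover counting error only, and a difference between the tables could give such rises. The largest falls were in Angptl7 (log2 -6.79), Clca3a1 (-5.98), Mgp (-5.69), Ptn (-5.59), Fbxo32 (-5.56), Gadd45g (-5.44), Rgs2 (-5.44), Upk3b (-5.42) and Nkain4 (-5.28). In all, 14503 of 16810 genes were called, 8341 higher and 6162 lower, and 9950 changed at least 2-fold. Among genes with at least 1 CPM without apoptotic cells 3945 were higher and 5912 lower. The groups did not overlap for 86.7% of genes, where chance gives 10%. Of 13255 genes called in both genotypes, 13181 (99.4%) had the same direction, and the log2 fold changes correlated with r = 0.969 across the 16810 genes. The contrasts share no library, but both cross the same 2 tables. A difference between the tables enters both alike and could give this likeness by itself. The median of all genes was 0.32, or 0.41 with DESeq2 size factors and -0.12 with a length correction, which left 14257 called genes with 46.5% of them higher.

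The interaction tests whether the KO effect differed between the conditions. A positive value means that the libraries labelled KO stood higher relative to WT with apoptotic cells than without. The largest were in Plet1 (log2 5.12, SE 1.18, at no count in KO alone, so its size is no bound), Fpr1 (2.86, SE 0.19), Adgre4 (2.77), Ms4a4a (2.49) and Fpr2 (2.17). The largest negative values were in Sfrp5 (-2.52, SE 0.26), Htr2b (-2.14), Cdh3 (-2.09), Nrn1 (-1.95) and Foxs1 (-1.85). Among efferocytosis genes, Mfge8 was at -1.78 (adjusted p = 2.1e-10), Marco at 1.77, Itgav at 0.76 and the scavenger receptor Stab1 at 0.63, and that list had 7 of 31 positive and 2 negative (also 7 and 2 adjusted over the list alone, camera adjusted p = 0.201). In all, 2132 of 16810 genes were called, 1269 positive and 863 negative, with 330 of at least 2-fold, of which 95 were positive and 235 negative. The joint fit pools the spread of both conditions (common biological coefficient of variation 0.0839, against 0.117 without and 0.0294 with apoptotic cells alone). What this does to the p-values was not tested, since the simulated counts were drawn from the same fit. The count was 1409 without KO library 2, 4330 without KO 3, 1129 without WT 3, 1356 without KO + AC 1, 1245 without KO + AC 2 and 1266 without WT + AC 2.

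Of 32 lists, 11 had a called interaction, none of them with an estimated correlation. Fibroblast and stromal markers had 9 of 12 negative (10 adjusted over the list alone, camera adjusted p = 2.01e-13, adjusted p = 0.073 with an estimated correlation), led by Acta2 (-1.61) and Col3a1 (-1.58). Cell cycle genes had 15 of 32 negative (21, and 1 positive, adjusted over the list alone, camera adjusted p = 1.27e-10, adjusted p = 0.073 with an estimated correlation), led by Ube2c (-1.07) and Cdc20 (-0.95). Matrix genes had 11 of 24 negative and 3 positive (13 and 3 adjusted over the list alone, camera adjusted p = 5.1e-08, adjusted p = 0.073 with an estimated correlation). Sparc was at -1.19. Osteoclast markers had 3 of 8 negative and 1 positive (4 and 1 adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.073 with an estimated correlation). Ctsk was at -1.33. The class II list had 5 of 11 members positive (6 adjusted over the list alone, camera adjusted p = 0.000221, adjusted p = 0.258 with an estimated correlation). Cd74 was at 0.86 and Cd86, a member that is not a class II gene, at 0.94. Engulfment genes had 7 of 29 positive (8, and 1 negative, adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.196 with an estimated correlation). Cybb was at 0.71. NF-kB targets had 9 of 25 positive and 2 negative (12 and 2 adjusted over the list alone, camera adjusted p = 0.00286, adjusted p = 0.258 with an estimated correlation). Cxcl2 was at 1.46. Monocyte markers had 2 of 10 positive, F13a1 (2.02) and Hp (1.39) (3, and 1 negative, adjusted over the list alone, camera adjusted p = 0.00989, adjusted p = 0.0954 with an estimated correlation). Mitochondrially encoded genes had 2 of 13 positive (3 adjusted over the list alone, camera adjusted p = 0.000296, adjusted p = 0.494 with an estimated correlation), and nuclear oxidative phosphorylation genes had 3 of 26 negative (also 3 adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.574 with an estimated correlation). Immediate early genes had 5 of 25 positive and 1 negative (6 and 2 adjusted over the list alone, camera adjusted p = 0.0494, adjusted p = 0.258 with an estimated correlation). That call ended with DESeq2 size factors (adjusted p = 0.0586, range over the alternatives 6.91e-06 to 0.258) and without KO library 1 (0.0523), 2 (0.0512) or 3 (0.105), WT 1 (0.183), KO + AC 3 (0.0922), and WT + AC 2 (0.0549) or 3 (0.0994), and that of monocyte markers without KO + AC 3 (0.0579).

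**Figure D2:**
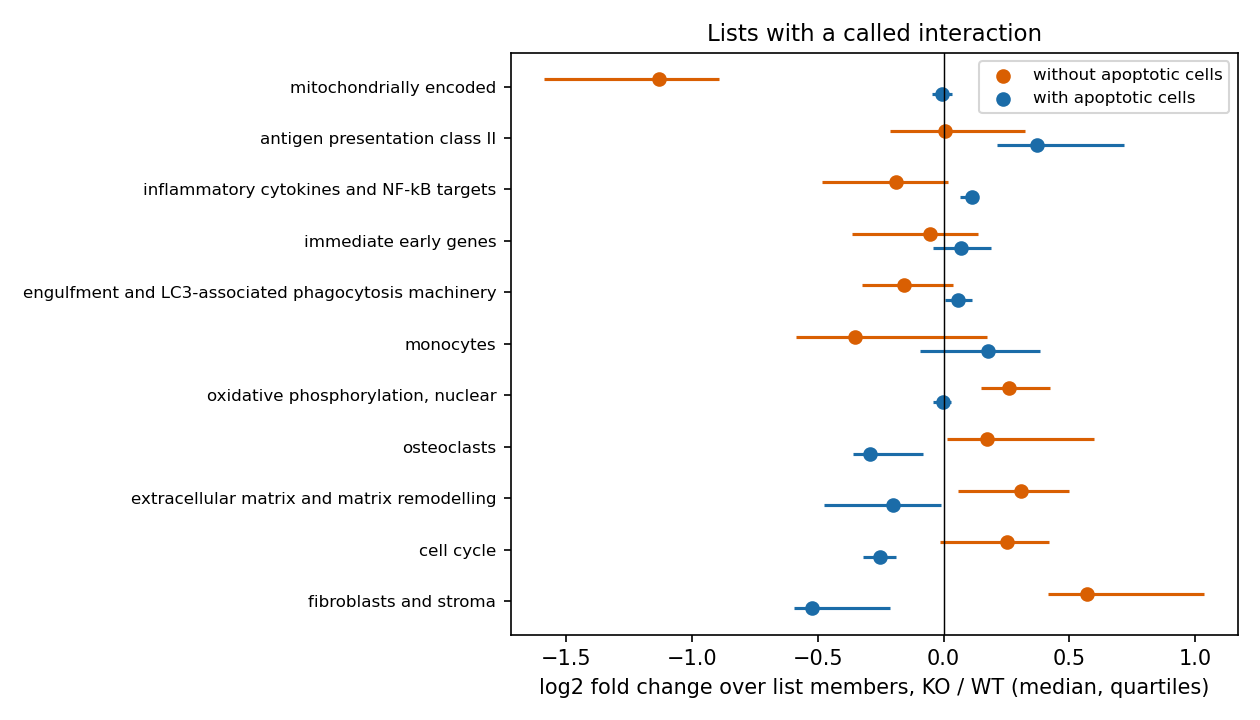
Log2 fold change of KO against WT over the members of the 11 lists with a called interaction, without (orange) and with (blue) apoptotic cells, where points are medians and lines run from the lower to the upper quartile of the members. Fibroblast and stromal markers had a median of 0.57 without and -0.52 with apoptotic cells, and cell cycle genes 0.25 and -0.25.

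The log2 fold changes of the libraries labelled KO against WT in the 2 separate fits, which share no library, correlated negatively across 12125 genes (Pearson r = -0.146, Spearman rho = -0.162). Of 382 genes called in both conditions, 309 (80.9%) went opposite ways. Higher in KO without and lower with apoptotic cells were 119 genes where independence gives 56.2, and 190 went from lower to higher where it gives 87.9. Higher in both were 41 where it gives 81.4, and lower in both were 32 where it gives 60.7.

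**Figure D3:**
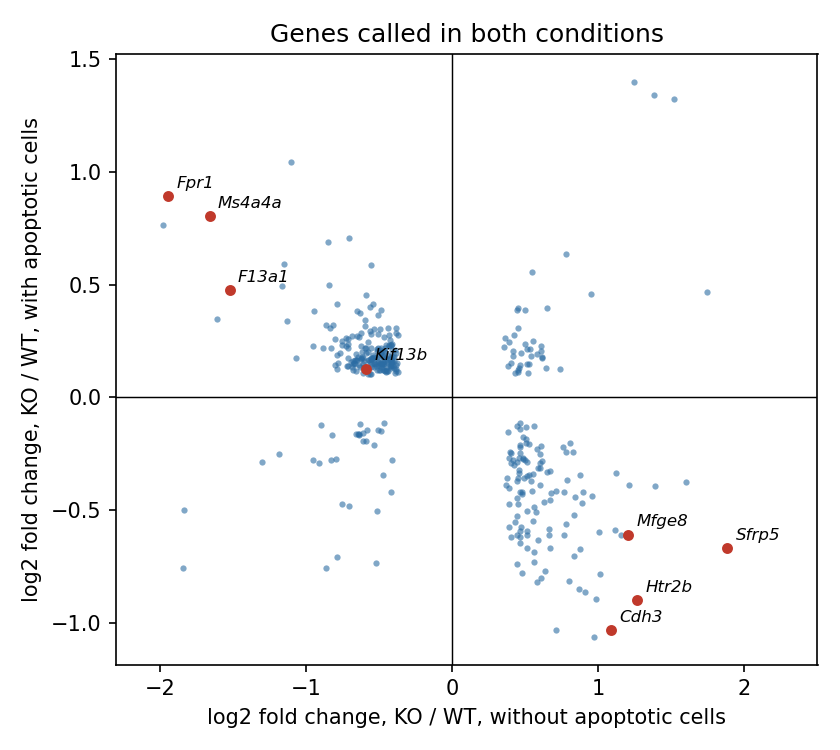
Log2 fold change of KO against WT without (horizontal axis) and with (vertical axis) apoptotic cells, for the 382 genes called in both comparisons, with 8 named genes in red. Of these genes 309 lie at the upper left and lower right, among them Kif13b at -0.59 and 0.13 and Mfge8 at 1.202 and -0.61.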

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

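The tests of exchanged labels, of apoptotic cells turning the effect around, of length and GC trends as the whole cause, of stromal cells and of other splits of the libraries were chosen after the results were seen. The test of the calls that ended with the length and GC correction was set before its own outcome was seen. That correction was itself chosen after the data were seen. The results here stand out because the effect of the libraries labelled KO against WT differed between the conditions by the interaction test of edgeR. Fpr1 had a log2 fold change of -1.95 without and 0.89 with apoptotic cells (interaction 2.86, adjusted p = 9.77e-11, n = 3 per group), Fpr2 -1.10 and 1.05 (2.17, adjusted p = 2.47e-06), Ms4a4a -1.66 and 0.81 (2.49, adjusted p = 5.62e-05), the adhesion receptor Adgre4 -1.98 and 0.77 (2.77, adjusted p = 4.13e-05) and F13a1 -1.52 and 0.48 (2.02, adjusted p = 2.81e-09). Kif13b itself had -0.59 and 0.13 (0.74, adjusted p = 0.000815). Opposite in sign were Sfrp5 with 1.88 and -0.67 (-2.52, adjusted p = 4.01e-07), Htr2b with 1.27 and -0.90 (-2.14, adjusted p = 2.76e-07), Cdh3 with 1.09 and -1.03 (-2.09, adjusted p = 1.98e-06), Nrn1 with 1.60 and -0.37 (-1.95, adjusted p = 0.00208) and the transcription factor Foxs1 with 0.99 and -0.90 (-1.85, adjusted p = 0.000282).

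The 11 lists with a called interaction, none of which was called with an estimated correlation (adjusted p = 0.073 to 0.574), had these medians over their members: fibroblast and stromal markers -1.05, cell cycle -0.48, extracellular matrix -0.44, osteoclasts -0.43, nuclear oxidative phosphorylation -0.23, monocytes 0.18, engulfment and LC3-associated phagocytosis 0.21, immediate early genes 0.27, NF-kB targets 0.35, class II 0.43 and mitochondrially encoded genes 1.05. The median KO effect itself was 0.57 without and -0.52 with apoptotic cells for fibroblast and stromal markers, 0.31 and -0.20 for the matrix, and 0.17 and -0.29 for osteoclast markers. The shortest 1440 genes had a median interaction of -0.28, so the -0.23 of nuclear oxidative phosphorylation does not by itself separate that list from the trend with length. Its interaction call was kept with the length corrections.

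A first pattern is that the KO effects ran in opposite directions in the 2 conditions. Length and GC trends of the form that the correction removes are argued against as its cause. After the correction, 79.44% of the genes then called in both conditions went opposite ways. Trends of another form were not tested. Exchanged genotype labels in 1 of the 2 tables stay open: Kif13b was higher by 0.13 on the log2 scale in the libraries labelled KO with apoptotic cells, the direction an exchange needs, but by less than the change of -0.59 without them. The opposite directions themselves are what an exchange would explain and do not count for it. An effect of KIF13B loss that apoptotic cells turn around, with 2132 called interactions, cannot be told apart from a difference between the tables, because the condition and the table coincide.

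A second pattern is the large number of genes that differed between KO and WT without apoptotic cells. Length and GC trends of the form that the correction removes are argued against as the whole cause by 740 genes called after it. Of these, 489 were among the 2045, and 488 of the 489 had the same direction. The simulation left 15 false calls, but its trends had the form that the correction removes. Trends of another form therefore stay open. For the 1556 calls that ended with the correction, the median absolute log2 fold change went from 0.527 to 0.22, and more than 2-fold down for 1012 of them. Their median SE went from 0.148 to 0.102. These genes were picked by their calls having ended, so whether the trends were the source stays open. More stromal cells in the libraries labelled KO stay open as a source. The 7 abundant stromal genes other than Acta2 did not share 1 log2 fold change (chi-square p = 1.48e-05), such as Col3a1 (1.00), Dcn (0.14) and Pdgfra (0.06), the last 2 chosen after their values were seen. This test cannot decide, since expression of the same genes in macrophages or a different kind of stromal cell would also make the changes unequal. It also treats genes of the same libraries as independent. A change within the stromal cells and an effect of KIF13B in macrophages stay open as well, as untested.

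Other splits of the libraries were counted for each result. For KO against WT and for apoptotic cells against none, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split called 2045 genes in KO against WT without apoptotic cells, 1866 with them, 14286 for apoptotic cells in WT and 14503 in KO, and the highest other split called 0 in each, so 1 split of 10 reached the real count. For lists, the real split called 8 without apoptotic cells (2 of 10 splits as many, highest other 9), 14 with them (1 of 10, highest other 6), 9 for apoptotic cells in WT (4 of 10, highest other 10) and 8 in KO (6 of 10, highest other 9). For the interaction, 1 of 60 drawn splits gave as many as 2132 genes, the real one, and the highest other gave 668. For its 11 lists, 4 of 60 gave as many (highest other 13), so chance was not excluded. The drawn splits combine the same 10 splits of each table and are not independent, so these shares are not p-values. For the correlation of -0.146 between the KO effects, 4 of 100 pairs of splits gave one as far from 0, the real pair among them (highest other 0.162). The pairs also reuse the 10 splits of each table, so chance was not excluded.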

How the results depend on the processing

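The length correction, the length and GC correction, the fits without KO libraries 1 and 2 and the restriction to genes of at least 1 CPM were chosen after seeing the data. Where no reason is given, the cause was not tested.

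A minimum of a 2-fold change, which by construction can only lower a count, left 160 genes for KO against WT without and 28 with apoptotic cells, 9221 for apoptotic cells in WT, 9950 in KO and 330 for the interaction. The joint fit of the 12 libraries, with 1 estimate of spread for both conditions, called 3999 KO against WT genes without and 157 with apoptotic cells. DESeq2 called 1137 with apoptotic cells (853 higher, 284 lower), and the cause was not tested. Without apoptotic cells, 740 genes were called after the length and GC correction (396 higher, 344 lower) and 95 without KO libraries 1 and 2, a fit with 1 KO library that is assumed to vary like WT. Under the length and GC correction Rgs1 turned to 0.10 (adjusted p = 0.683) and Chordc1 to 0.0725 (adjusted p = 0.679), neither called.

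Leaving out 1 library at a time gave 312 to 4166 genes for KO against WT without apoptotic cells (312 without KO 1, 698 without KO 2, 4166 without KO 3, 1001 without WT 2, 370 without WT 3) and 1192 (without KO + AC 1) to 2142 with them. It gave 14165 to 14528 for apoptotic cells in WT and 14458 to 14893 in KO. For the interaction it gave 1129 (without WT 3) to 4330 (without KO 3), with 1409 without KO 2, 1356 without KO + AC 1, 1245 without KO + AC 2 and 1266 without WT + AC 2. Fewer libraries lower the power of a test, but the rises without KO 3 have a cause that was not tested. KO 3 was closer to WT 1 (chi-square of the counts per degree of freedom 9.08) than to KO 1 (24.8) or KO 2 (38.7).

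Of the lists, camera with an estimated correlation called 0 for KO against WT without and 1 with apoptotic cells, 0 for apoptotic cells in WT and in KO and 0 for the interaction, where the preset correlation called 8, 14, 9, 8 and 11. With fry, 7 lists were called for KO against WT with apoptotic cells, 27 for apoptotic cells in WT and 24 in KO. Leaving out 1 library gave 4 (without KO 3) to 9 lists for KO against WT without apoptotic cells. The correlation of the KO effects was -0.167 after the length and GC correction, -0.174 without KO libraries 1 and 2, and -0.164 to -0.107 without 1 library (-0.107 without KO 3, -0.109 without KO + AC 2, -0.122 without WT + AC 2), so its sign held in each of these.

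DESeq2 size factors, no filter, a block for the replicate number and the length correction left the 5 gene counts within 1.5-fold, as did a fit of the 6 compared libraries for the effect of apoptotic cells. With the block the counts were 2496, 1649, 14246, 14453 and 2174. The replicate numbers do not pair the libraries, since same-numbered libraries of 2 groups correlated with -0.107 to 0.0639 and not every library was closest to its own number. A window of 20 Mb around Kif13b gave odds ratios of 0.865 and 1.04. With 17000976 to 18770757 counts per library, simulated 1.5-fold changes were recovered for 62% of genes without and 88% with apoptotic cells and for 43% in the interaction, so smaller differences could go uncalled.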

Other observations

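The tests of RNA from Jurkat cells and of a background in proportion to length were chosen after the results were seen. Several stress and metabolic lists moved both ways with apoptotic cells in WT macrophages and were not called. Heat shock genes had 4 of 13 higher and 6 lower (camera adjusted p = 0.666), with Hspa1b at log2 3.67 and Hspb1 at -2.82. NRF2 targets had 2 of 15 higher and 11 lower (adjusted p = 0.077), with Txnrd1 at 1.72 and Prdx1 at -1.20. Genes of glycolysis and hypoxia had 5 of 20 higher and 13 lower (adjusted p = 0.197), with the hexokinase Hk2 at 1.71 and Aldoa at -1.21. The integrated stress and unfolded protein responses had 6 of 19 higher and 9 lower (adjusted p = 0.522), with the cystine transporter Slc7a11 at 5.00. Sterol synthesis had 6 of 24 higher and 13 lower (adjusted p = 0.0881), and transport kinesins 15 of 24 higher and 7 lower (adjusted p = 0.666), with Kif21b at 1.99 and Kif19a at -3.52. Counts adjusted over each list alone were identical for these 6 lists.

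A further pattern is that genes of T cells and of other tissues had counts with apoptotic cells. Marker genes of 6 tissues or cell types were looked up. Median levels without and with apoptotic cells were 0.0706 and 7.24 CPM for 20 T cell leukaemia genes, 0.0331 and 0.335 for B cell and killer lymphocyte genes, 0 and 0.0805 for hepatocyte, 0.00998 and 0.409 for neuron, 0.0152 and 0.35 for heart muscle and 0 and 0.115 for pancreas and gut genes. Of the T cell leukaemia genes, 13 of 17 that were under 1 CPM without apoptotic cells reached it with them, against 3 of 19 B cell and killer lymphocyte genes (Fisher's exact p = 0.000557). The most abundant of these 17 with apoptotic cells, chosen after their values were seen, were Lef1 (0.00998 to 26.3 CPM), Lck (0.878 to 24.0) and Zap70 (0.107 to 21.5), while Cd3d stayed at 0.0449 and 0.0427.

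Of these 17 T cell leukaemia genes, 11 lay above 1.61 CPM, the 99th percentile of 5878 protein-coding genes that were silent without apoptotic cells. Some of the 17, such as Lck, had counts without apoptotic cells, unlike the silent genes. The T cell leukaemia genes also include Lef1, Myb and Skap1, already named for their rises. The 11 and the Fisher's exact test partly reuse that selection. They therefore cannot decide against a background over all genes in proportion to length as the source of the T cell genes. RNA of the Jurkat cells may also be the source of the T cell genes (Fisher's exact p = 0.000557), although reads were not tested against the human genome here. The list of genes nearly identical in human and mouse, which such RNA would raise if its share were large, had 22 of 31 lower with apoptotic cells in WT and 20 of 31 lower in KO. For the genes of other tissues, a background in proportion to length stays open as the source. The level of silent genes rose with exonic length (Spearman rho = 0.63), from a median of 0.00826 CPM in the shortest to 0.136 in the longest 4th. This cannot decide, since CPM are not divided by length and longer genes gather more counts from other sources as well. A biological source in the macrophages was not tested.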
